A study of Mus musculus with 2 samples.

How the data were processed

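The series holds 2 droplet libraries from embryoid bodies of the mouse embryonic stem cell line E14 Tg2a. Per the labels' protocols, cells of differentiation day 0 and days 2, 3, 4, 5 and 6 were dissociated, cryopreserved, thawed on one day and mixed in equal parts, and the libraries followed the 10x Genomics 3′ v3.1 chemistry. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode as the authors made them, not normalized. Per the submitters' processing notes the counting tool was Cell Ranger 7.1.0 and the genome build mm10, while the matrix headers name Cell Ranger 7.0.0. The gene annotation was not given in the sources used here; all IDs were looked up in the GRCm38 annotation, whose coordinates are printed. The lowest UMI total of any barcode was 500 in replicate 1 and 504 in replicate 2, so the matrices had been limited to barcodes called as cells. Both libraries belong to one group, and the labels call them biological replicates. The library was a block in the test, which removes differences shared by all classes of a library. The p-values therefore measure how differences between classes vary between these 2 libraries, with the spread estimated over all classes of a fit.

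Of the deposited barcodes, 5415 in replicate 1 and 4335 in replicate 2, those with at least 1000 genes and at most 15% mitochondrial UMIs passed (2370 and 2806). The mitochondrial limit was exceeded by 2762 barcodes (51.0%) of replicate 1 and 1362 (31.4%) of replicate 2, and 2154 and 814 had under 1000 genes, with some barcodes failing both. Doublets were scored per library with Scrublet as in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes, which took 103 and 97. This left 2267 cells (41.9% of barcodes) with 73792582 UMIs in replicate 1 and 2709 (62.5%) with 76827741 in replicate 2. The labels' aim of 10000 cells per replicate has another denominator.

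Genes to be tested were kept out of the clustering. Tested genes that vary together with the markers are still tied to the naming of the classes. Of 32285 genes, 16902 were reserved for testing: 725 genes of 28 lists, 1026 genes whose symbols match fixed patterns of transcription factor names, and every gene whose Ensembl ID has an even md5 hash. The 154 marker genes of 27 cell types were never tested, and the 13 mitochondrially encoded genes were neither clustered on nor tested. Clustering used the other genes: the 2000 most variable, log counts per 10000, 30 principal components, 15 neighbours and the Leiden method at resolution 1. All steps were run in double precision, and of 20 random starts the partition of highest modularity was taken. This choice of 20 starts was made after a partition from a single start had been seen to change with the rounding of the processor; a single start is among the alternatives. The libraries were clustered together as they are.

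A cluster took the name of the class whose markers had the highest mean log2 fold of its CPM over that of all cells, with 5 CPM added, if this mean reached 0.75 and at least 3 markers were detected (at least 10 CPM and a UMI in at least 10% of cells). A general neuron name was given only where no particular neuron class passed. A cluster whose median UMI total was below the library's median divided by 3 in both libraries stayed unnamed. The markers were fixed, but these thresholds were set after the clusters had been seen, and the clusters they keep out of every class held 37.7% of replicate 1 and 30.3% of replicate 2. Clusters named p3 and pMN progenitor-like together form the neural progenitor-like class, and they are compared with each other by cluster number.

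UMI counts were summed per library and class. Genes with at least 5 CPM in both libraries of at least 1 class were scaled with TMM factors and tested with edgeR 4.0.16's quasi-likelihood test and Benjamini-Hochberg adjustment over the reserved genes, with the library as a block, since cells of all classes in a library shared one suspension and one run. A gene was called at an adjusted p below 0.05 and an absolute log2 change of at least 1. A planned single fit became 3: one over 7 classes with at least 30 cells per library (12944 genes, 7065 reserved, 722 of them transcription factors, 6 residual degrees of freedom), one with p3 and pMN progenitor-like cells apart (13004, 7093 and 725, with 7), and one with clusters 1, 3 and 13 added after they were seen (13277, 7227 and 733, with 10). CPM in the report are scaled by the factors of the fit in question and differ slightly between fits. The standard error is the size of the log2 change divided by the square root of the test's F statistic. It is no direct measure of spread. Where a class holds few counts of a gene, it can be smaller than the counting error. Values of single libraries can lie further apart than it shows. A planned comparison of caudal epiblast-like cells was not run, as no cluster took that name, and the planned comparison of other neurons with motor neurons was that of V3 interneuron-like cells.

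Lists were tested among the reserved genes with camera (limma 3.58.1), with a preset correlation of 0.01 and again with an estimated one, adjusted over the 28 lists, and called members were counted also after adjustment over the list alone. The lists were naive pluripotency regulators, Hox paralogs 1 to 5 and 6 to 13, ventral progenitor domain regulators, neurogenic factors, motor neuron subtype factors, the Hedgehog, retinoid, Notch, FGF, Wnt and TGF-beta, Nodal and BMP pathways, DNA replication, mitosis, cell cycle exit and D-type cyclins, glycolysis, nuclear oxidative phosphorylation, synaptic vesicles, axon guidance, neuronal cytoskeleton, voltage-gated channels, neurotransmitter synthesis and transport, imprinted genes, methylation and heterochromatin, the Lin28, let-7 and RNA-binding switch, dissociation and heat-shock stress, p53 targets and apoptosis, and adhesion. Named genes follow a fixed rule. Per comparison these are the 6 transcription factors with the largest rise and the 6 with the largest fall among those called, up to 2 risen and 2 fallen members of each list, and the 3 largest rises and falls among other genes with a symbol. All have a fold in the same direction in both libraries and at least 20 CPM in the higher class. Genes named as leading a cluster or as members of a list's short count, such as Uhrf1, follow from the values. Leading genes were ranked over all genes on the same cells, so a test of such a gene between clusters is no separate evidence. Some genes that the rule names are not reported here.

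Shares of cells carry exact Clopper-Pearson intervals. A class with no UMI of a gene was set to a floor of 3 counts over the class, and with 1 to 3 UMIs the ratio is given with its exact counting interval. Both use the counts of the 2 libraries pooled and without TMM scaling, so they differ from ratios of the printed CPM; intervals and floors cover counting error only. Values of 1 library alone are edgeR's log2 ratio with 0.125 counts added, scaled to library size, and have no test, since 1 library leaves no residual degrees of freedom. The libraries were checked against each other: chi-square per degree of freedom over genes was between 1.94 (fibroblast-like) and 8.11 (p3 progenitor-like).

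The test was run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from reserved genes with a mean of at least 20 CPM over the 2 classes, above the filter of 5 CPM. Counts were independent draws from the fit's own class means and spread, without a library effect. The compared classes shared the mean of both for all other genes, and changes up and down were equal in number. In the data many more genes were called. The rates thus show how the model recovers its own draws. For neural progenitor-like against pluripotent-like cells it called 99% of the 4-fold and 47% of the 2-fold genes, which lie at the limit of 1, and 6 of 6692 unchanged genes. For V3 interneuron-like against motor neuron-like cells the values were 99%, 50% and 4 of 6736. When the cells of one class were split at random into 2 parts, edgeR called 0 genes for neural progenitor-like cells (144 of 7073 at an unadjusted p under 0.05) and 0 for motor neuron-like cells (324 of 7088). Those parts differed by the sampling of cells alone, so few calls could arise. The split does not show the error rate for classes made by clustering.

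Other settings fixed with the design were DESeq2 1.42.0, relative log expression factors, no CPM filter, no library block, equal numbers of cells per class, stricter cell filters (8% mitochondrial UMIs, 2000 genes), looser ones (25%, 500 genes), no doublet removal, Leiden resolutions 0.5 and 2, clustering on all genes or on the other hash group, genes centred within each library, each library left out, and the estimated correlation. Chosen after seeing the data were leaving out the 4 clusters with a median mitochondrial share over 8%, and a single random start. All cells of a library shared one droplet run, so free RNA can add UMIs of abundant genes to every class. In addition, cryopreservation and thawing can remove fragile cells, which would affect shares.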

Results

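Mouse embryonic stem cells of the line E14 Tg2a were turned into ventral spinal cord cells in embryoid bodies, which are free-floating aggregates, under retinoic acid, a signal that gives neural cells a caudal identity, and an agonist of smoothened, which switches on the Hedgehog pathway. The series title names regulatory transcription factors of differentiation as its subject. Cells of day 0 and of days 2, 3, 4, 5 and 6 were frozen, thawed together, mixed in equal parts and run as 2 droplet libraries. The labels call these libraries biological replicates 1 and 2 of one group, and no map from single cells to days was used here, so the comparisons are between cell classes within the mixture. The labels give 10000 cells per replicate as the aim. The count matrices held 5415 barcodes with 90160605 UMIs in replicate 1 and 4335 barcodes with 88494009 UMIs in replicate 2. After filtering, 2267 and 2709 cells were kept, with medians of 27923 and 22928 UMIs and of 6137 and 5738 genes per cell.

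The kept cells fell into 21 clusters, 14 of which were named from markers fixed before the data were examined. Pluripotent-like cells (clusters 8 and 9, led by Esrrb and Tdh) made up 4.54% ± 1.00 of the cells (SD, n = 2), and primed epiblast-like cells (clusters 5 and 15, led by Utf1 and Bnc2) 7.87% ± 0.591. The clusters named p3 progenitor-like (clusters 2 and 11, led by Adgrb3 and Fgfbp3) made up 14.6% ± 3.63, and pMN progenitor-like cells (cluster 6, with Olig2 and Nkx6-2, factors of the domain that makes motor neurons) 7.81% ± 2.12. Neuronal precursor-like cells (cluster 10, led by the proneural factor Neurog2) made up 5.61% ± 0.619 and motor neuron-like cells (cluster 0, led by the neurofilament genes Nefm and Nefl) 4.93% ± 0.291. V3 interneuron-like cells (cluster 18, with Sim1, a factor of this ventral interneuron type) were 1.94% of replicate 1 (exact 95% binomial interval 1.41 to 2.60) and 3.99% of replicate 2 (3.28 to 4.79). Floor plate-like cells (clusters 4 and 16, with Shh, the ventral morphogen) were 13.9% (12.5 to 15.4) and 19.4% (17.9 to 20.9). The intervals of the replicates did not overlap for these 2 classes, nor for p3, pMN progenitor-like and fibroblast-like cells and clusters 1 and 7; intervals cover counting error only. Endoderm-like and fibroblast-like clusters held 27 cells each and entered no comparison. The 7 unnamed clusters (1, 3, 7, 12, 13, 14 and 17) held 37.7% of replicate 1 and 30.3% of replicate 2. No cluster took the caudal epiblast-like name. Among the markers of that state, T averaged at most 1.78 CPM (UMI counts scaled to a common library total) in any class or cluster. Cdx1, another of them, was highest in pluripotent-like cells and next in cluster 1. The other markers of the state are not given here, so these levels do not show whether it was present or absent. Shares of neuronal precursor-like cells came to 9.43% under stricter cell filters and 2.89% with clustering on the other genes, and that of primed epiblast-like cells to 4.94% under looser filters. The plot of class shares shows both libraries side by side.

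**Figure D1:**
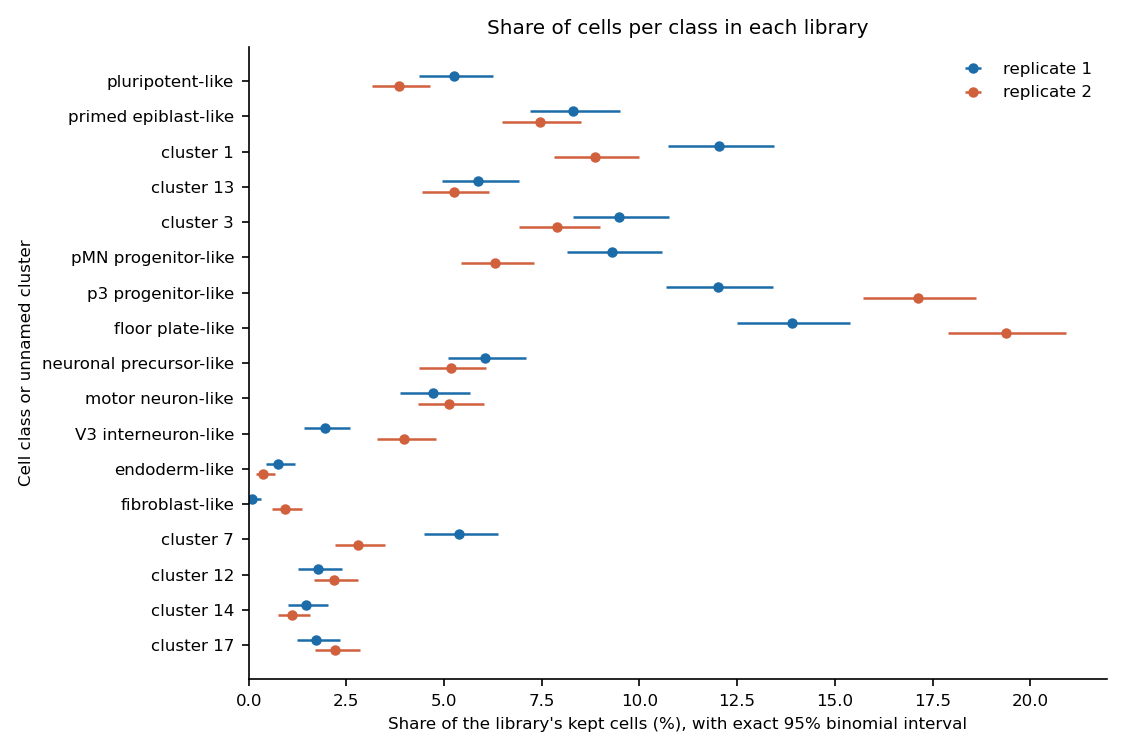
Share of kept cells in each cell class, in percent of the library's kept cells, with replicate 1 and replicate 2 as separate points and exact 95% binomial intervals as bars. Floor plate-like cells took 13.9% and 19.4% and V3 interneuron-like cells 1.94% and 3.99%, while motor neuron-like cells took 4.72% and 5.13%.

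Neural progenitor-like cells (clusters 2, 6 and 11) were compared with pluripotent-like cells, the state from which the cultures start, to ask which transcription factors separate them. Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633 in GRCm38, protein coding), a homeobox factor of naive pluripotency, averaged 218 ± 13.7 CPM (SD, n = 2) in pluripotent-like cells and 0.170 ± 0.0364 in neural progenitor-like cells, a log2 change of -10.17 ± 0.21 (SE, adjusted p = 7.7e-12). Few counts lie behind the progenitor value, so this SE can be smaller than its counting error. Hoxb4 (ENSMUSG00000038692, chromosome 11, 96318267 to 96321638), a homeobox factor that sets position along the hindbrain and neck, went the other way, from 0.688 ± 0.0663 to 149 ± 4.36 CPM (7.73 ± 0.23, adjusted p = 2.7e-11). Rorb (ENSMUSG00000036192, chromosome 19, 18930605 to 19111196), an orphan nuclear receptor, averaged 87.2 ± 30.4 CPM in progenitors with 1 UMI over all pluripotent-like cells, a ratio of 839 with a counting interval of 150.4 to 33147. The POU factor Pou3f2 rose by 8.24 ± 0.28 on the log2 scale, while Esrrb, a nuclear receptor of the naive network, was at 231 ± 9.01 CPM in pluripotent-like cells and 0.510 ± 0.109 in progenitors. Aqp3, a water channel, was at least 844-fold lower in progenitors, against a floor of 3 counts over the class, and Fam181a at least 105-fold higher. Taken alone, replicate 1 gave a log2 change of 7.31 for Pou3f2, and replicate 2 held no UMI of it in pluripotent-like cells.

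Of 16 naive pluripotency regulators tested, 15 fell and 1 did not pass, with a median log2 change of -6.74 (camera adjusted p = 2.4e-23). The pluripotent-like class was named from markers of the same state, so this fall largely follows from the naming and is no separate evidence. All 13 Hox genes of paralogs 1 to 5 rose (1.2e-15). Among 9 Hox genes of paralogs 6 to 13, which pattern the trunk, 4 rose, such as Hoxb8 (6.48 ± 0.21), 2 fell and 3 were not called. That list was not called (adjusted p = 0.0967), and its median was 1.27, or 0.47 with the 3 genes of fewest counts at their bound. Neurogenic factors had 16 of 23 higher, a call that was lost with an estimated correlation (camera adjusted p = 3.0e-05, adjusted p = 0.114 with an estimated correlation). In the Hedgehog list, 11 of 13 genes rose, including the target Hhip (5.39 ± 0.34) and the coreceptor Gas1 (3.90 ± 0.28), and Gli2, a transcriptional effector, fell (-2.46 ± 0.21). Its call was also lost (0.00285, adjusted p = 0.152 with an estimated correlation). In the retinoid list 9 of 17 rose, such as the binding protein Crabp2 (6.34 ± 0.33), and 2 fell, among them the receptor Rarg (-4.29 ± 0.19), with adjusted p = 0.00453 and adjusted p = 0.114 with an estimated correlation. Axon guidance genes had 31 of 46 higher and 5 lower (2.2e-07), with Epha3 at 7.61 ± 0.53 (6.89 in replicate 1 alone and 8.37 in replicate 2 alone).

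Of 24 glycolysis genes 14 fell, such as the glucose transporter Slc2a3 (-6.41 ± 0.24) and the kinase Pfkp (-6.33 ± 0.20), and none rose (0.00375, adjusted p = 0.433 with an estimated correlation). Neither edgeR nor DESeq2 called any of 54 nuclear oxidative phosphorylation genes (34 at an unadjusted p under 0.05 in edgeR, 33 of them also adjusted, with log2 changes within 1), and the list was not called (camera adjusted p = 0.0599). Of 31 S phase genes 2 fell, Ung and Uhrf1 (adjusted p = 0.396), and of 30 mitosis genes 2 rose and 2 fell (0.754). Among 15 genes of cell cycle exit and D-type cyclins, 6 rose and 4 fell (0.126), and within them Ccnd2 rose from 2.99 ± 1.81 to 789 ± 122 CPM while Ccnd1 fell (-1.66 ± 0.20). Imprinted genes had 15 of 27 higher, such as H19 (6.82 ± 0.68) and Nnat (6.21 ± 0.22), and 2 lower, among them Phlda2 (-5.43 ± 0.31), with adjusted p = 0.000667 and adjusted p = 0.114 with an estimated correlation. Replicates 1 and 2 alone gave 7.67 and 8.67 for Ccnd2 and 6.12 and 7.65 for H19. The call of Uhrf1 was lost without the CPM filter (-0.95, adjusted p = 1.0e-08) and with 44 cells per class and library, where the change came just short of the limit of 1 (adjusted p = 9.4e-05), and that of Ccnd1 with clustering on the other genes (-0.99). The counts of all these lists were the same when adjusted over the list alone. In all, 1579 of 7065 tested genes were higher and 1295 lower, and of 722 transcription factors 218 were higher and 161 lower. The naive, Hox 1 to 5 and axon guidance calls held with an estimated correlation.

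Primed epiblast-like cells, which resemble the epiblast just before its germ layers form, were set against pluripotent-like cells to ask what separates the earliest step. Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443), a methyltransferase that sets new DNA methylation, averaged 353 ± 4.30 CPM in primed and 25.1 ± 5.00 in pluripotent-like cells (3.80 ± 0.13, adjusted p = 1.1e-09). Lef1, a factor that carries Wnt signals to target genes, was at 169.8 ± 18.1 against 6.08 ± 1.67 CPM (4.79 ± 0.17, adjusted p = 1.1e-09). Bcl11a, a zinc finger factor, averaged 79.1 ± 5.73 CPM with 1 UMI in all pluripotent-like cells, a ratio of 692 (124 to 27369). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), a naive pluripotency factor, fell from 185 ± 3.79 to 2.85 ± 0.150 CPM (-6.02 ± 0.25, adjusted p = 2.5e-09), and Tfcp2l1, another, from 424 ± 10.2 to 5.55 ± 1.25. The immediate early genes Fos (-5.67 ± 0.51) and Fosb (-4.98 ± 0.53) were lower as well.

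Of the 16 naive regulators 13 fell and 1, Mycn, rose (1.83 ± 0.23), with adjusted p = 2.8e-27. Naming the pluripotent-like class by markers of that state set much of this fall in advance. Of 26 methylation and heterochromatin genes 3 rose, Dnmt3a and Uhrf2 (1.29 ± 0.10) among them, and 1 fell, the demethylase gene Tet2 (-2.21 ± 0.16), while Dnmt3b, a marker of the class, was not tested. The list was not called (adjusted p = 0.534), its median was below 0 and its mean and test direction above. In the FGF list 5 of 17 rose, such as the feedback phosphatases Dusp4 (4.43 ± 0.21) and Dusp6 (2.87 ± 0.24), and 1 fell (0.00536, adjusted p = 0.125 with an estimated correlation). Of 20 p53 targets and apoptosis genes 7 rose, such as Pmaip1 (4.09 ± 0.25), which promotes cell death (0.00513, adjusted p = 0.270 with an estimated correlation). In the stress list 8 of 22 fell and 1 rose (0.0118, adjusted p = 0.180 with an estimated correlation). Adhesion genes had 9 of 22 higher, among them the epithelial splicing factor Esrp1 (5.59 ± 0.36) and the adhesion protein Epcam (2.97 ± 0.17), and 4 lower, among them Zeb1 (-1.73 ± 0.19), with adjusted p = 0.0122 and adjusted p = 0.145 with an estimated correlation. The Wnt list had 5 higher, such as Sfrp2 (3.12 ± 0.49), and 5 lower of 26, such as the target gene Axin2 (-2.23 ± 0.25), and was not called (0.785). The TGF-beta, Nodal and BMP list, with 5 higher and 8 lower of 21, was not called either (0.962), and in it Id2 rose (3.42 ± 0.45) while Bmp4 (-3.96 ± 0.33) and Id1 (-2.21 ± 0.26) fell. The libraries differed for Esrp1 (6.40 and 5.03 in replicates 1 and 2 alone) and Id2 (2.75 and 4.58). Adjusted over the list alone the counts were the same. In all, 912 genes were higher and 767 lower, with 112 and 99 transcription factors, and the naive list was the only one of the 28 called with an estimated correlation.

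Neuronal precursor-like cells were compared with neural progenitor-like cells to ask what separates them. The progenitor class pools p3 and pMN progenitor-like cells in a mix that differed between the libraries. The pMN progenitor-like cells were 211 of its 483 cells in replicate 1 and 171 of 635 in replicate 2. The comparison thus does not separate neuron formation from differences of domain or stage. Ebf2 (ENSMUSG00000022053, chromosome 14, 67233292 to 67430918), a factor of newborn neurons, averaged 434 ± 55.1 CPM in precursors and 4.46 ± 1.72 in progenitors (6.58 ± 0.20, adjusted p = 4.5e-10). Nhlh2, a basic helix-loop-helix factor, was at 151 ± 17.8 against 1.26 ± 0.153 CPM (6.88 ± 0.20, adjusted p = 4.5e-10), and Lhx3, a LIM homeobox factor of motor neurons, at 51.7 ± 0.419 against 0.235 ± 0.129. Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796), a Notch target that keeps cells in the progenitor state, fell from 75.5 ± 7.05 to 10.9 ± 0.683 CPM (-2.80 ± 0.29, adjusted p = 1.5e-05). Id3, an inhibitor of helix-loop-helix factors, fell as well (-3.40 ± 0.39). Crym, a thyroid hormone binding protein, had no UMI in precursors and was at least 51.9-fold lower there, though its progenitor level varied between the libraries (21.7 ± 18.8 CPM). In replicates 1 and 2 alone the log2 change was 7.18 and 6.12 for Ebf2 and 8.32 and 7.22 for Lhx3.

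Of 23 neurogenic factors 18 rose and 1 fell (camera adjusted p = 2.4e-51). The precursor class was named from markers of the same step, such as Neurog2, so much of this rise follows from the naming. Synaptic vesicle genes had 16 of 34 higher and 1 lower (2.0e-10), such as Syt4 (3.24 ± 0.26), which acts in transmitter release. Neuronal cytoskeleton genes had 17 of 32 higher and none lower (5.5e-17, adjusted p = 0.0709 with an estimated correlation), including the neurofilaments Nefm (4.16 ± 0.24) and Nefl (4.36 ± 0.22). In the list of Lin28, let-7 and RNA-binding genes 7 of 23 rose, such as the neuronal splicing regulators Rbfox3 (4.50 ± 0.32) and Srrm4 (4.56 ± 0.22), and none fell (2.1e-05). Of these 4 calls all but that of the cytoskeleton list held with an estimated correlation. The Notch list went both ways, 5 higher and 5 lower of 19, and was not called (0.117). In it Mfng (3.20 ± 0.16), a modifier of Notch receptors, rose and the receptor Notch3 fell (-1.73 ± 0.34). Of 15 cell cycle exit genes and D-type cyclins 3 rose, with the inhibitor Cdkn1c (2.26 ± 0.10) and Ccnd1 (2.03 ± 0.21) among them, and 2 fell, Ccnd3 (-1.72 ± 0.14) and Ccnd2 (-1.86 ± 0.19), with adjusted p = 0.249. Calls were lost for Ccnd1 with clustering on the other genes (0.29, adjusted p = 0.478), for Ccnd2 at a clustering resolution of 0.5 (-0.67), and for Ccnd3 (-0.58) and Notch3 (-0.80, adjusted p = 0.0735) under stricter cell filters. Replicates 1 and 2 alone gave 4.83 and 3.65 for Nefm and 3.98 and 2.65 for Syt4. The cytoskeleton list had 18 higher when adjusted over the list alone, and the other counts were the same. In all, 431 genes rose and 424 fell, with 54 and 58 transcription factors. The stricter cell filters left 428 genes called in place of 855, and at a clustering resolution of 0.5 the share of higher genes was 39.8% in place of 50.4%.

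Motor neuron-like cells were compared with neuronal precursor-like cells to ask what separates the 2 classes. The precursor markers are not particular to the motor neuron lineage, and days are mixed, so the comparison does not separate maturity from lineage. Motor neuron-like cells were named from motor neuron markers such as Isl1 and Mnx1, so higher motor neuron factors follow in part from the naming. Lhx4 (ENSMUSG00000026468, chromosome 1, 155698031 to 155751684), a LIM homeobox factor that acts with Lhx3 in motor neurons, rose from 15.6 ± 3.98 CPM in precursors to 191 ± 58.5 in motor neuron-like cells (3.60 ± 0.22, adjusted p = 7.5e-08). Rxrg, a retinoid X receptor, averaged 40.1 ± 10.9 CPM, with 2 UMIs in all precursors and a ratio of 134 (36.8 to 1110). Neurog1 (ENSMUSG00000048904, chromosome 13, 56250478 to 56252163), a proneural factor, fell from 80.5 ± 2.45 to 2.14 ± 0.378 CPM (-5.19 ± 0.27, adjusted p = 2.3e-08), and so did Neurod4 (-3.83 ± 0.24), another, and Id1 (-4.91 ± 0.25), an inhibitor of such factors. Neurod4 came to -3.31 in replicate 1 alone and -4.52 in replicate 2 alone.

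All 30 mitosis genes fell, with a median of -3.81 (camera adjusted p = 2.6e-40), among them Hmmr (-4.66 ± 0.30) and Cenpf (-4.30 ± 0.33). All 31 S phase genes fell too, with a median of -2.32 and Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, at -3.89 ± 0.16, with a camera adjusted p of 7.0e-29. Both calls were lost with an estimated correlation (adjusted p = 0.0810 and adjusted p = 0.0581 with an estimated correlation). Neuronal cytoskeleton genes had 26 of 32 higher (1.5e-30), such as Prph (5.44 ± 0.36) and Stmn4 (4.99 ± 0.14). Synaptic vesicle genes had 25 of 34 higher and 1 lower (6.3e-14), with Sncg at 5.34 ± 0.27. Of 29 voltage-gated channel genes 21 rose and none fell (1.4e-08), such as the sodium channel subunits Scn3b (4.79 ± 0.48) and Scn2a (4.65 ± 0.34). Of 14 genes of transmitter synthesis and transport 6 rose, such as Slc10a4, a carrier of synaptic vesicles (5.38 ± 0.26), and Th, the enzyme that starts dopamine synthesis (5.52 ± 0.45), and 3 fell (0.194). In the Hedgehog list 8 of 13 fell, such as Hhip (-4.27 ± 0.25), and 1 rose, the coreceptor Gas1 (1.88 ± 0.18), with adjusted p = 0.000303 and adjusted p = 0.0697 with an estimated correlation. In the Notch list 9 of 19 fell, such as Notch1 (-3.19 ± 0.15), and 3 rose (0.00325, adjusted p = 0.0892 with an estimated correlation). Imprinted genes had 8 of 27 higher, such as Meg3 (4.17 ± 0.26), and 5 lower, such as Grb10 (-1.71 ± 0.11), and were not called (0.232). In replicates 1 and 2 alone the values were 4.67 and 6.26 for Prph, 5.47 and 4.55 for Scn3b, 3.97 and 5.39 for Scn2a, 6.28 and 4.69 for Slc10a4 and 3.52 and 4.84 for Meg3. The cytoskeleton, synaptic and channel calls held with an estimated correlation. The Notch list had 10 lower when adjusted over the list alone, and the other counts were the same. In all, 964 genes rose and 843 fell, with 72 and 99 transcription factors.

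V3 interneuron-like cells, the glutamatergic neurons born ventral to motor neurons, were compared with motor neuron-like cells. They came from 44 and 108 cells with medians of 14191 and 14690 UMIs, against 107 and 139 motor neuron-like cells with 30306 and 29356. Neurog3 (ENSMUSG00000044312, chromosome 10, 62133090 to 62134763), a proneural factor, averaged 116 ± 42.0 CPM in V3 interneuron-like and 1.94 ± 2.75 in motor neuron-like cells (5.78 ± 0.61, adjusted p = 1.8e-05). Hoxb9 (ENSMUSG00000020875, chromosome 11, 96271457 to 96276595), a homeobox factor of the thoracic cord, was at 43.5 ± 19.6 against 2.94 ± 2.65 CPM (3.84 ± 0.33, adjusted p = 3.1e-06). Robo3, a receptor of axons that cross the midline, rose by 5.04 ± 0.44 on the log2 scale, and Slc17a8, a vesicular glutamate transporter, had 3 UMIs in motor neuron-like cells and a ratio of 207 (69.5 to 1014), with V3 levels of 85.7 ± 75.8 CPM. Lhx4 fell from 191 ± 58.5 to 5.22 ± 5.28 CPM (-4.68 ± 0.33, adjusted p = 6.1e-07), and Lhx3, with 1 UMI in V3 interneuron-like cells, was lower by a ratio of 92.4 (16.5 to 3658). Replicate 1 held no UMI of Neurog3 in motor neuron-like cells, and replicate 2 alone gave 5.22 for it. The libraries also differed for Hoxb9 (4.77 in replicate 1 alone and 3.57 in replicate 2 alone), Robo3 (6.55 and 4.77) and Lhx4 (-7.28 and -4.06).

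Of the 9 Hox genes of paralogs 6 to 13, 6 rose, Hoxb9 among them, and none fell (camera adjusted p = 8.7e-06, adjusted p = 0.0884 with an estimated correlation). Ventral domain regulators had 6 of 9 lower and none higher, such as Irx5 (-3.99 ± 0.41), with adjusted p = 0.000115 and adjusted p = 0.121 with an estimated correlation. Of 16 motor neuron subtype factors 7 fell and 2 rose, with Bcl11b at 2.68 ± 0.41 (0.00361, adjusted p = 0.0884 with an estimated correlation), and the list's median was 0.07 while its mean was -1.10 and its test direction down. Motor neuron-like cells were named from markers such as Isl1 and Mnx1, and V3 interneuron-like cells from markers such as Sim1 and Slc17a6. Changes in motor neuron factors, such as Lhx3 and Lhx4, and in Slc17a8 are thus tied to the naming and no separate evidence. Neuronal cytoskeleton genes had 14 of 32 lower, such as Nefm (-4.85 ± 0.24), and 1 higher, Map2 (1.12 ± 0.21), with adjusted p = 1.5e-19 and adjusted p = 0.0664 with an estimated correlation. In the Notch list 8 of 19 rose, such as Dlk1 (3.82 ± 0.26) and Hes1 (2.49 ± 0.51), and none fell (5.9e-06, adjusted p = 0.0798 with an estimated correlation). Markers of neuronal precursors gave cluster 18 its second-best name (mean log2 fold 1.996 against 3.42), and cell cycle genes went the same way: 6 of 30 mitosis genes (2.4e-05, adjusted p = 0.473 with an estimated correlation) and 2 of 31 S phase genes (0.00361, adjusted p = 0.531 with an estimated correlation) were higher and none lower. The class also held Pkd2l1 (24.0 ± 6.10 CPM without TMM scaling) and Gata2 (40.8 ± 35.2), genes of another neuron type, which contacts the cerebrospinal fluid. This comparison separates neither maturity nor an admixture of that type from V3 identity. Axon guidance genes had 19 of 46 lower, such as Robo2 (-3.96 ± 0.20), and 8 higher (0.00110, adjusted p = 0.103 with an estimated correlation). The transmitter list had 5 higher, such as Calca (4.78 ± 0.49), and 4 lower of 14, such as Sst (-6.61 ± 0.36), and was not called (0.834), with a median of 0.09 against a mean of -0.17 and a test direction up. The call of Map2 was lost at a clustering resolution of 0.5 (0.96) and with genes centred within each library (0.99). Replicates 1 and 2 alone gave 3.81 and 1.55 for Hes1 and -2.94 and -4.73 for Irx5. Adjusted over the list alone the axon guidance list had 9 higher, the Notch list 10 higher, the motor neuron subtype list 3 higher and the mitosis list 4 higher, and the other counts were the same. In all, 481 genes rose and 486 fell, with 66 and 49 transcription factors, and camera called no list with an estimated correlation (9 at an unadjusted p under 0.05).

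Floor plate-like cells, the ventral midline cells that secrete Shh, were compared with neural progenitor-like cells. That progenitor class pools p3 and pMN progenitor-like cells in a mix that differed between the libraries. Foxj1 (ENSMUSG00000034227, chromosome 11, 116330704 to 116335399), the forkhead factor that switches on genes of motile cilia, averaged 23.0 ± 8.19 CPM in floor plate-like cells and 2.04 ± 0.339 in progenitors (3.47 ± 0.27, adjusted p = 1.0e-06). Dnah9, a dynein chain of motile cilia, was at 116 ± 14.4 against 0.659 ± 0.728 CPM (7.38 ± 0.36, adjusted p = 3.5e-08). Hoxd4 (ENSMUSG00000101174, chromosome 2, 74711929 to 74729160) fell from 140.2 ± 27.1 to 12.2 ± 1.18 CPM (-3.52 ± 0.12, adjusted p = 2.2e-09), and Hoxd3 (-3.02 ± 0.18), Irx3 (-3.52 ± 0.33) and Gli2 (-2.73 ± 0.31) were lower with it. The annotated spans of Hoxd4 and Hoxd3 overlap, so that their counts cannot be fully told apart. The immediate early gene Fos was called higher (1.98 ± 0.30, adjusted p = 2.4e-04), but its level varied between the libraries, with 196 ± 184 CPM against 47.1 ± 38.6. In replicates 1 and 2 alone the log2 change was 9.34 and 6.72 for Dnah9 and -3.36 and -2.18 for Gli2.

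The Wnt list had 4 higher and 4 lower of 26 and was not called (camera adjusted p = 0.709), with the ligands Wnt4 (3.84 ± 0.31) and Wnt7b (2.99 ± 0.26) higher and the secreted modulator Sfrp1 (-2.16 ± 0.10) lower. Adhesion genes had 5 of 22 higher, such as Pcdh8 (5.20 ± 0.32) and Cdh1, the epithelial cadherin (3.31 ± 0.20), and 4 lower, such as Ncan (-1.99 ± 0.24). That list was not called (0.255), with a median of -0.08 against a mean of 0.05 and a test direction up. Of 20 p53 targets and apoptosis genes 5 fell, such as Eda2r (-1.54 ± 0.20) and Phlda3 (-1.37 ± 0.14), and none rose (0.00112, adjusted p = 0.491 with an estimated correlation). Of the Hox genes of paralogs 1 to 5, 2 of 13 fell, Hoxd4 and Hoxd3 (0.00205, adjusted p = 0.491 with an estimated correlation). Ventral domain regulators had 1 higher and 4 lower of 9 (0.182), and the stress list 7 higher and 2 lower of 22 (0.629). For these 6 lists the counts were the same when adjusted over the list alone. In all, 549 genes rose and 317 fell, with 46 and 48 transcription factors, and camera called no list with an estimated correlation (0 at an unadjusted p under 0.05). With 44 cells drawn from each class and library, 56 factors were called in place of 94, and the calls of Eda2r (-1.51, adjusted p = 0.121) and Phlda3 (-0.78, adjusted p = 0.125) were lost. Phlda3 was also lost at a clustering resolution of 0.5 (-0.49), and Wnt4 came to 4.59 and 3.28 in replicates 1 and 2 alone.

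The progenitor clusters 2 and 11 (p3 progenitor-like) were compared with cluster 6 (pMN progenitor-like). Their names are those of neighbouring domains that make V3 interneurons and motor neurons, but they are given by number because the leading genes of clusters 2 and 11 held Sox9 and Fabp7, which are general neural progenitor markers, and none of their own markers Nkx2-2, Nkx2-9 and Nkx6-1, while those of cluster 6 held its own Olig2 and Nkx6-2 beside Nkx2-9. Sox5 (ENSMUSG00000041540, chromosome 6, 143828425 to 144781977), an SRY-box factor, averaged 517 ± 85.7 CPM in clusters 2 and 11 and 56.8 ± 3.49 in cluster 6 (3.16 ± 0.13, adjusted p = 1.9e-09). Nfia, a factor of the later switch to glia, was at 606 ± 165 against 65.3 ± 0.149 CPM (3.19 ± 0.25, adjusted p = 3.6e-07). Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974), a Hedgehog effector and target, fell from 32.7 ± 0.741 to 3.90 ± 1.99 CPM (-3.13 ± 0.25, adjusted p = 4.1e-07), and Gas1, a Hedgehog coreceptor, from 48.3 ± 2.72 to 3.72 ± 0.799. Ndst3, an enzyme of heparan sulfate modification, was at least 93.2-fold higher in clusters 2 and 11. In replicates 1 and 2 alone the log2 change of Gli1 was -2.60 and -3.73.

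In the Hedgehog list 5 of 13 fell and 1 rose (camera adjusted p = 0.00366, adjusted p = 0.145 with an estimated correlation). Of 17 FGF genes 8 rose, such as the receptor Fgfr3 (2.42 ± 0.22) and Dusp6 (2.37 ± 0.20), and 3 fell (6.6e-05, adjusted p = 0.0604 with an estimated correlation). In the Notch list 6 of 19 rose, such as Hey1 (2.41 ± 0.18) and the ligand Jag1 (1.87 ± 0.18), and none fell (0.00312, adjusted p = 0.102 with an estimated correlation). Of 31 S phase genes 6 fell, such as Ung (-1.87 ± 0.16), and none rose (2.8e-16, adjusted p = 0.117 with an estimated correlation). Of 13 Hox genes of paralogs 1 to 5, 3 fell, such as Hoxa4 (-1.82 ± 0.20), and none rose (0.000421, adjusted p = 0.150 with an estimated correlation). Adjusted over the list alone the counts were the same. In all, 721 of 7093 genes rose and 347 fell, with 83 and 48 of 725 transcription factors, and camera called no list with an estimated correlation (8 at an unadjusted p under 0.05). With 44 cells drawn from each class and library 604 genes were called in place of 1068, and 74.4% of the called factors were higher in place of 63.4%.

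**Figure D2:**
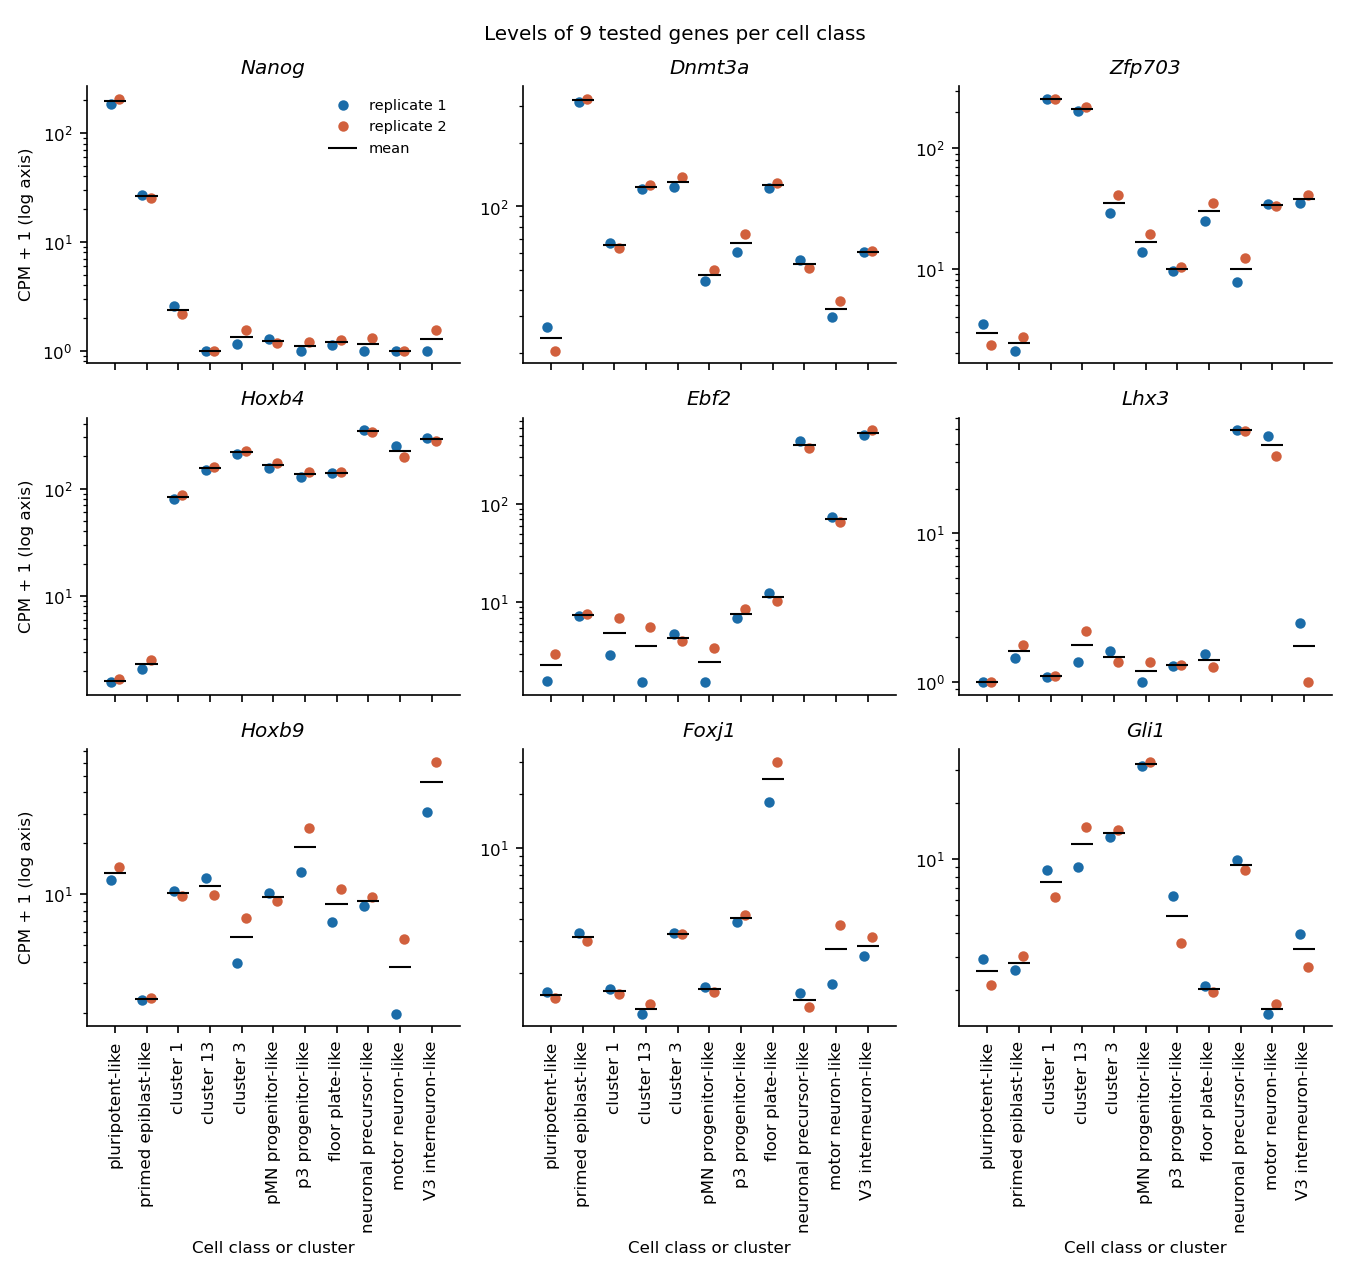
CPM per cell class or cluster for 9 tested genes, taken from the summed counts without TMM scaling and drawn on a log axis of CPM + 1, with replicate 1 and replicate 2 as separate points and a line at their mean. Nanog was highest in pluripotent-like cells (196 ± 14.7 CPM) and Dnmt3a in primed epiblast-like cells (319 ± 8.23), while Ebf2 was at 405 ± 49.8 in neuronal precursor-like and 536 ± 46.6 in V3 interneuron-like cells.

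After the clusters were seen, 3 comparisons were added for large unnamed clusters, which are given by number. A rise of a gene already known to lead its cluster, such as Stra8 or Nrg1, is no separate evidence. Cluster 1, led by Stra8 and Tll1, was compared with primed epiblast-like cells. Zfp703 (ENSMUSG00000085795, chromosome 8, 26977325 to 26981461), a zinc finger factor, averaged 254 ± 2.60 CPM in cluster 1 and 1.60 ± 0.492 in primed epiblast-like cells (7.31 ± 0.20, adjusted p = 2.8e-14). Cyp26a1 (ENSMUSG00000024987, chromosome 19, 37697798 to 37701536), the enzyme that breaks down retinoic acid and is induced by it, was at 166 ± 2.23 against 1.22 ± 0.257 CPM (7.07 ± 0.29, adjusted p = 2.8e-12). Stra8, named for its induction by retinoic acid, was at 1706 ± 39.0 against 22.7 ± 0.443 CPM. Lef1 fell from 174 ± 18.7 to 2.72 ± 0.00420 CPM (-6.00 ± 0.15, adjusted p = 2.3e-14), and the FGF-responsive factors Etv4 (-5.09 ± 0.14) and Etv5 (-4.78 ± 0.14) fell too. All 14 Hox genes of paralogs 1 to 5 rose, with Hoxb4 at 5.78 ± 0.18 (camera adjusted p = 2.3e-19), and 7 of 10 of paralogs 6 to 13 (0.0112, adjusted p = 0.0846 with an estimated correlation), with none lower. Retinoid genes had 10 of 17 higher and 2 lower (0.000103). Naive regulators had 10 of 16 lower, such as Nanog (-4.34 ± 0.20), and 1 higher (0.00133). Of 26 methylation and heterochromatin genes 5 fell, such as Dnmt3l (-3.11 ± 0.18) and Tet1 (-2.63 ± 0.12), and none rose (0.00133). All of these calls but that of paralogs 6 to 13 held with an estimated correlation. The FGF list had 9 of 17 lower, such as Spry2 (-3.31 ± 0.24), and 4 higher (0.00133, adjusted p = 0.110 with an estimated correlation). Adjusted over the list alone the counts were the same. In all, 1112 of 7227 genes rose and 713 fell, with 136 and 109 of 733 transcription factors.

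Cluster 13, led by Tagln and Acta2, was compared with cluster 1. Nr2f2 (ENSMUSG00000030551, chromosome 7, 70351944 to 70366735), an orphan nuclear receptor, averaged 169.8 ± 12.7 CPM in cluster 13 and 7.83 ± 1.90 in cluster 1 (4.42 ± 0.16, adjusted p = 1.2e-11), and its relative Nr2f1 rose by 3.33 ± 0.24 on the log2 scale. Cyp26b1, another enzyme that breaks down retinoic acid, was at 141 ± 15.9 against 12.9 ± 2.32 CPM (3.48 ± 0.34, adjusted p = 1.1e-06). Lefty1, a secreted inhibitor of Nodal, fell from 27.8 ± 3.95 to 2.34 ± 0.954 CPM (-3.54 ± 0.30, adjusted p = 2.5e-07). Of the 14 Hox genes of paralogs 1 to 5, 10 rose, such as Hoxd4 (2.63 ± 0.23) and Hoxc5 (2.30 ± 0.13), and none fell (camera adjusted p = 1.2e-27). Motor neuron subtype factors had 7 of 16 higher (7.5e-09), the TGF-beta, Nodal and BMP list 13 higher and 2 lower of 22 (0.000497), with Id3 at 2.55 ± 0.28, and the retinoid list 5 higher and 1 lower of 17 (0.000739). The Hedgehog list had 3 of 13 higher, Gas1 among them (3.35 ± 0.14), and none lower (8.0e-06). These 5 calls held with an estimated correlation. Adjusted over the list alone the counts were the same. Hoxd4 came to 3.25 in replicate 1 alone and 1.92 in replicate 2 alone. In all, 296 genes rose and 398 fell, with 72 and 35 transcription factors. With 44 cells drawn from each class and library 429 genes were called in place of 694, and 56.2% of them were higher in place of 42.7% (82.4% of the called factors in place of 67.3%).

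Cluster 3, led by Nrg1 and Gpc3, was compared with cluster 6 (pMN progenitor-like). Nrg1 (ENSMUSG00000062991, chromosome 8, 31814551 to 32884029), a secreted ligand of ErbB receptors, averaged 1825 ± 101 CPM in cluster 3 and 53.1 ± 27.5 in cluster 6 (5.06 ± 0.36, adjusted p = 6.3e-08). Wnt4 was at 33.1 ± 3.65 against 2.44 ± 0.768 CPM (3.78 ± 0.45, adjusted p = 7.1e-06) and Cdh1 at 41.9 ± 1.07 against 3.91 ± 0.464 (3.40 ± 0.25, adjusted p = 6.8e-08). Hoxd4 fell from 203 ± 7.01 to 44.5 ± 2.48 CPM (-2.19 ± 0.13, adjusted p = 2.2e-08), and Pou3f2 (-1.77 ± 0.15) fell with it. Adhesion genes had 5 of 22 higher and 2 lower (camera adjusted p = 0.000923, adjusted p = 0.164 with an estimated correlation), and retinoid genes 4 of 17 higher, such as Stra6 (2.42 ± 0.20), and 1 lower, Crabp1 (-1.53 ± 0.38; -2.19 and -0.94 in replicates 1 and 2 alone), with the list not called (0.0579). The p53 list had 3 of 21 lower, such as Bbc3 (-1.15 ± 0.11) and Phlda3 (-1.12 ± 0.10), and none higher (0.000757, adjusted p = 0.173 with an estimated correlation). Of the 31 S phase genes edgeR called 0 (27 at an unadjusted p under 0.05) and DESeq2 called 1, while their list was called down (9.2e-11, adjusted p = 0.173 with an estimated correlation). Members of the adhesion list called higher were 6 when adjusted over the list alone, and the other counts were the same. Nrg1 came to 4.71 and 5.70 in replicates 1 and 2 alone. In all, 483 genes rose and 147 fell, with 52 and 38 transcription factors. With 44 cells drawn from each class and library 398 genes were called in place of 630.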

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

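Chosen only after the result was seen were the tests of free RNA, of undifferentiated cells and of depth within cluster 7 for the Zscan4 cells, of leaky cells and doublets for the clusters of high mitochondrial share, and of swapped molecules and free RNA for the shared barcodes. Each result here is a signal that the report's comparisons do not use, above the limit of 3 counts that a count of 0 allows, though clusters 8 and 15 and the 2 Zscan4 cells of cluster 1 belong to compared groups.

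UMIs of the Zscan4 family, genes of a rare embryo-like state of embryonic stem cells, came to 1032 in kept cells, and 13 cells with 5 or more held 96.8% of them in replicate 1 and 95.1% in replicate 2. Of these cells 11 lay in cluster 7, an unnamed cluster of low UMI totals that entered no comparison, and since the family's copies are nearly identical, counts between the copies are uncertain. The values argue against free RNA from other cells, since the top 20 cells held at least 10.04 times the share of the family's UMIs that draws by depth give. Whether the 13 cells are remaining undifferentiated cells stays open. The pluripotent-like class held 0 UMIs of the family, so it gives no marker level for undifferentiated cells in this state. The 13 cells did hold fewer markers of that class. These were at 0.132 of its level in replicate 1 (5 cells, 95% bootstrap interval 0.0960 to 0.156) and 0.3031 in replicate 2 (8 cells, 0.0921 to 0.542). The latter interval is past the bound of 0.5 first set but below the 0.8 set for the explanation. Of the 13 cells 1 reached 0.5 of that level. None was in that class (the test first planned, which 13 cells are too few to decide), and Nanog, at 195.6 CPM there, had 0 UMIs (at most 7.65 CPM by 3 counts). Doublets of such a cell with another one cannot be told apart from single cells, as median UMI totals were 0.471 of those of other cells of clusters 1 and 7 in replicate 1 (0.228 to 1.51) and 1.115 times theirs in replicate 2 (0.776 to 1.43), with both intervals past the bound of 1.2, while against the shallow rest of cluster 7 alone the ratios were 4.62 (2.52 to 6.23) and 7.71 (4.83 to 11.8), and no biological explanation was tested, as the design has 1 group.

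Barcodes over the limit of 15% mitochondrial UMIs, which entered no comparison, held 8032 UMIs of neuron markers, and among kept cells clusters 8 and 15 (median mitochondrial shares of 10.9% and 10.3%) stood beside clusters 9 and 5 of the same names. Against these partners the median log2 fold was higher in the longest 10% of genes than in the shortest 10% by at least 2.77 in both pairs and libraries, so clusters 8 and 15 may hold leaky cells that kept nuclear RNA, while median UMIs of at most 0.367 of the partner's argue against doublets. For the excluded barcodes the values argue against free RNA alone, which would let at most 1% exceed Poisson draws for neuron markers: of those with 500 or more nuclear-encoded UMIs, 5.64% of 1561 did in replicate 1 (exact 95% interval 4.55 to 6.90) and 7.16% of 1033 in replicate 2 (5.67 to 8.91), though the interval of replicate 1 reaches below the 5% bound set beforehand. Whether neurons were lost more than other cells stays open: neuron marker CPM at 0.710 and 0.4418 of those in kept cells met the bound of 1 set beforehand, but Malat1, a nuclear RNA, was at 2.45 and 2.28 times, so markers could be low through lost cytoplasm, motor neuron markers were at 1.41 and 0.978, and barcodes that failed only the gene minimum held 3030 and 3263 CPM against 1279 and 1746. What raised the mitochondrial share stays open, and no biological explanation was tested.

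The libraries shared 118 barcodes, and in 113 of these pairs the depths lay 50-fold or more apart. The shallower barcode held a median of 0.602% of the UMIs of its partner in 85 pairs and 0.445% in the other 28, and none of the shallower ones was among the kept cells. Among all deeper barcodes it correlated best with its own partner in 100% and 96.43% of pairs, a value consistent with molecules swapped between the sequenced libraries. Free RNA of the shallower barcode's own library is argued against, as it correlated better with that library's summed profile in 4.42% of pairs. Whether the libraries were sequenced together is not stated in the sources used here, and no biological explanation was tested.

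The endoderm-like cluster held 465 UMIs of Gata6. In the fibroblast-like cluster there were 694 UMIs of Col3a1. Both genes are among the markers that name such clusters, so these counts follow from the naming.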

How the results depend on the processing

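Chosen only after the result was seen were the tests without the clusters of high mitochondrial share, those with a single random start in clustering, and all tests of clusters 1, 3 and 13. No fold change of a named gene reversed its direction under any of the settings run. The balance of calls did turn for cluster 13, where 56.2% of called genes were higher with 44 cells per class and library in place of 42.7%, and for neuronal precursor-like cells at resolution 0.5 (39.8% in place of 50.4%). Of the values for named genes, 1955 kept direction and call and 12 kept direction but lost the call, all of them given in the report. With 1 library left out no test can be made, and 275 of the fold changes stayed within the SD of the 2 libraries while 25 moved beyond it, again without a change of direction. Neither outcome is evidence of stability. With 2 libraries each value lies close to their mean, relative to their own SD, by arithmetic. The naming rule also required the same direction in both libraries. For calls across all genes 110 counts stayed within 1.5 times the reported one and 4 did not, and for transcription factors 117 and 4.

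With 44 cells drawn from each class and library, a setting that holds fewer cells by construction, the counts were 56 transcription factors in place of 94 for floor plate-like cells, 604 genes and 78 factors in place of 1068 and 131 for clusters 2 and 11 against cluster 6, 429 genes in place of 694 for cluster 13, and 398 genes and 57 factors in place of 630 and 90 for cluster 3. Under stricter cell filters 428 genes and 64 factors were called for neuronal precursor-like cells in place of 855 and 112; the cause was not tested. DESeq2 gave 0.896 to 1.03 times the reported counts of genes, and for neural progenitor-like cells 2783 of the 2874 genes were called the same way. Without the CPM filter, where more genes are tested, the count there was 3925. Without the library block all counts of genes and factors stayed within 1.5 times, for example 824 genes in place of 855 for neuronal precursor-like cells, and 4 list calls changed: Notch in neural progenitor-like cells (adjusted p = 0.0249 without the block and 0.0511 with it) and ventral domain regulators in primed epiblast-like cells (0.0435 and 0.0689) and cluster 3 (0.0452 and 0.0562) were gained, and methylation in motor neuron-like cells (0.0612 and 0.0470) was lost.

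An estimated correlation between genes left fewer of the 28 lists called: 3 in place of 12 for neural progenitor-like, 1 in place of 12 for primed epiblast-like, 3 in place of 10 for neuronal precursor-like and 4 in place of 10 for motor neuron-like cells, 4 in place of 8 for cluster 1 and 8 in place of 15 for cluster 13. It left 0 in camera for V3 interneuron-like (16 reported, 9 at an unadjusted p under 0.05 with the estimate), and floor plate-like cells (3 and 0), for clusters 2 and 11 (15 and 8) and for cluster 3 (5 and 6). For these counts the cause was not tested.

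Class shares moved beyond the spread between libraries 21 times and stayed within it 77 times. That of motor neuron-like cells, 4.93% as reported, was 5.78% under stricter and 4.08% under looser cell filters, 6.65% without doublet removal, 7.08% and 4.25% at resolutions 0.5 and 2, 6.94% with all genes, 7.36% with genes centred, 7.04% with the other genes and 7.38% with a single start. For neuronal precursor-like cells (5.61%) it was 9.43% under stricter filters, 4.30% without doublet removal, 3.92% with all genes, 4.49% with genes centred and 2.89% with the other genes. Shares of pMN progenitor-like cells (7.81%) came to 11.2%, 10.4% and 11.3% under these last 3 settings. Neural progenitor-like cells as a whole (22.4%) came to 19.2% under looser filters, 16.4% at resolution 0.5 and 24.96% with all genes. Primed epiblast-like cells (7.87%) came to 4.94% under looser filters, where a cluster of 99 and 100 cells led by Lef1 and Bnc2, genes that also lead cluster 15, took an endothelial-like name. For these shares the cause was not tested. Of the cells in a named class, 85.2% to 96.3% had the same class under each of the 9 other partitions. Here pMN and p3 progenitor-like cells counted as one class, so moves between these 2 names are not seen in the percentages.

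Some settings gave no value. No cluster was pMN progenitor-like at resolution 0.5, and under stricter filters V3 interneuron-like cells were too few in replicate 1 (25). Clusters 1, 3 and 13 have no counterpart by number in other partitions, and with the other genes clustered only factors and list members stay untouched by the clustering. Genes under the chosen filter of 5 CPM, which have few counts at this depth, are tested only in the setting without it; the filter left 12944 of 32285 genes in the first fit, 7065 of them reserved and tested.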

Other observations

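No test in this part was planned, and none was run: it gives levels, chosen after their values were seen, mostly in cells that entered no comparison. Levels are CPM of summed counts without TMM scaling.

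Cluster 17 (39 cells of replicate 1 and 60 of replicate 2) carried factors of motor neurons that leave the brainstem through its branchial and visceral nerves. Phox2a averaged 531 ± 67.5 CPM (SD, n = 2) there against 6.31 ± 2.41 in motor neuron-like cells, Tbx20 45.7 ± 17.5 against 5.62 ± 0.736, and the receptor kinase gene Alk 660.2 ± 12.2 against 82.3 ± 40.9. The cholinergic enzyme gene Chat was at 173 ± 23.1 and 162 ± 17.5 CPM, while Mnx1, a factor of spinal motor neurons, was at 24.5 ± 4.87 and 110.3 ± 19.7. Hoxb4 (438 ± 70.7 CPM) and Hoxb8 (297 ± 60.2) were also present in cluster 17. Its median of 4961 UMIs kept it without a name, but in 6 of 9 other partitions a cluster of 26 to 68 cells took the name visceral or branchial motor neuron-like. Summed counts weigh cells by depth, so the levels may come from a part of the 39 and 60 cells of cluster 17.

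A 2-cell-like cluster of 11 to 16 cells, with markers of the Zscan4 and Tcstv families, was named in 3 of the 9 other partitions. Cluster 7, which held most of the Zscan4 cells, had a median of 3794 UMIs. The 13 cells with 5 or more Zscan4 UMIs also held 659 UMIs of Stra8, at 1679 CPM, close to the 1711 CPM in other cells of cluster 1 and above the 8.02 in pluripotent-like cells. Other genes differed from cluster 1: Tll1, which leads that cluster, was at 10.2 CPM in the 13 cells against 277 in its other cells. Cyp26a1 was at 803 against 168 CPM. Without doublet removal, a cluster of 116 and 73 cells of low UMI totals was led by the globin genes Hbb-y and Hba-x.

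Endoderm-like cells (17 and 10) held Gata6 at 369 ± 44.2 CPM, Gata4 at 267 ± 5.26 and Sox17 at 85.8 ± 13.1, factors of that germ layer, and the carrier protein gene Ttr at 112 ± 60.9. They also held Cyp26a1 at 334 ± 56.4. Fibroblast-like cells (2 and 25) held the collagen genes Col3a1 at 1024 ± 159 and Col1a1 at 334 ± 149 CPM, with Foxf1, a factor of visceral mesoderm, at 166 ± 105. All of these genes but Cyp26a1 and Foxf1 are markers of the class in question, so their presence follows from the naming.

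Markers of cell types outside the named classes appeared in V3 interneuron-like cells, where Pkd2l1, a channel gene of neurons that contact the cerebrospinal fluid, averaged 24.0 ± 6.10 CPM and Gata2, a factor of such neurons, 40.8 ± 35.2. Cdx1, a caudal homeobox gene, was highest in pluripotent-like cells (57.1 ± 6.46 CPM) and next in cluster 1 (9.44 ± 1.13). The serotonergic enzyme gene Tph2 reached at most 8.01 ± 3.88 CPM, in cluster 17 (8 UMIs).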
